A study of Felis catus with 36 samples.

How the data were processed

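RNA was measured by sequencing in 2 tissues of the cat, the left ventricle (LV) and skeletal muscle (SKM). Per the labels, the animals had aortic banding, a narrowing placed around the aorta that here serves as a feline model of heart failure with preserved ejection fraction, or a sham operation, and were sampled after 1 or 4 months. Each tissue has 18 libraries, 3 of sham at 1 month and 5 each of sham at 4 months, banded at 1 month and banded at 4 months, which makes 36 libraries. The libraries were made from total RNA with a stranded mRNA kit, per the labels. The labels name no sex, age, sequencing date or batch. They also do not say whether libraries of a group come from separate animals, so all p-values measure the spread between samples.

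The authors deposited 1 file of counts per library, with 26681 genes and 5 summary lines for reads not assigned to a gene. The count values are whole numbers and were not normalized by the authors. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.11.2 and DESeq2 1.22.2 were used, and neither a genome build nor an annotation release is stated. The authors also deposited 8 tables of comparisons, 4 per tissue. The deposited tables give, per gene, a mean normalized count (a signal on the scale of counts), a log2 fold change with its standard error, a test statistic (a score), a p-value and an adjusted p-value. These deposited tables were compared with fits of the deposited counts and entered no other fit.

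The counts were read as deposited, without the summary lines. Of the 26681 genes, 6013 had a count of 0 in all 36 libraries. Gene counts per library ran from 14.6 M to 22.3 M in LV and from 21.5 M to 35.0 M in SKM. Reads assigned to genes made up 46.1% to 63.8% of the lines counted per LV library and 56.3% to 76.3% per SKM library. Within groups, no pair of libraries among 66 pairs differed as little as repeated counts of the same library would, with 36.3 as the lowest chi-square per degree of freedom and 0 identical pairs.

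Genes are named in the counts by Ensembl identifiers. The reference table at hand lists 39307 cat genes by symbol and holds 0 Ensembl identifiers, so 0 of 26681 identifiers could be joined to a symbol, and the files do not pair them. Named genes were to be chosen by a fixed rule. It took genes with a symbol and an adjusted p under 0.05, up to 10 in each direction per banding comparison and up to 5 in each direction for the others, by the size of the fold change. It also asked for a mean of at least 1 CPM (counts scaled to a common library total) and, outside the differences of effects, for all libraries of a group on the same side of the other group's mean, and it added fixed heart and muscle genes. It named no gene, since none has a symbol here. The 33 fixed gene lists, of 884 symbols for pathways, contractile and metabolic genes and markers of other cell types, could not be tested for the same reason. The 4 identifiers printed in the text were chosen after their values were seen.

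For each tissue, edgeR 4.0.16 was fitted to all 18 libraries under R 4.3.3. Genes were kept with filterByExpr on the 4 groups, which left 13976 genes in LV and 13480 in SKM. Libraries were scaled by the trimmed mean of M values (TMM), and group means were fitted with the quasi-likelihood model. Contrasts were banded against sham at each time, 4 months against 1 month in each treatment, and the banding effect at 4 months minus that at 1 month. A fit of all 36 libraries, with 14579 genes, gave the banding effect in LV minus that in SKM at each time. Tests were two-sided, and genes were called at an adjusted p under 0.05 after Benjamini-Hochberg correction over the genes tested in that comparison. Fold changes are on the log2 scale with their standard error (SE). Log2 CPM values used a prior count of 2. Correlations of fold changes between comparisons are across genes, and genes are not independent replicates.

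Alternatives chosen before the data were examined were DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, scaling by relative log expression (RLE), no low-count filter, a fit of only the groups compared, replicate number as a block, and leaving out each library in turn. The comparisons, the rule for named genes and the splits of the samples into other groups were also fixed before the data were examined. Voom without quality weights, and fits with sham 1-month library 1 in place of sham 4-month library 1, were added after seeing the data. Library numbers are shared by LV and SKM libraries of a group. They were to count as pairs only if residuals of every LV and SKM library with the same number correlated above 0.1, which held for 11 of 18, and the best match of residuals across the tissues had the same number in 12 of 18 libraries. The labels do not say whether the tissues come from the same animals. Of 21 genes with 2 levels in both tissues, examined later, 15 had the same numbers high in both, and at most 8 did in 1000 shuffles. The fits without a block remain those reported first, as fixed beforehand, and for the difference between the tissues the fit with the number as a block is given beside them, which was decided after its result had been seen. Measures of single libraries were compared between groups by two-sided exact permutation tests with Benjamini-Hochberg correction.

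The models were tested on simulated data with the depth and spread of these libraries, with 200 changed genes per comparison. The counts were drawn independently for each gene and library, so structure that genes or libraries share is absent from them. Over the 12 comparisons, edgeR recovered 0% to 16.4% of genes changed 1.5-fold, 10.4% to 56.7% of those changed 2-fold and 60.6% to 90.9% of those changed 4-fold, with 1 to 8 false calls. DESeq2 recovered 19.4% to 71.6% of genes changed 2-fold, with 7 to 29 false calls, and voom with quality weights 8.96% to 58.2%, with 0 to 8 false calls. In other splits of the real samples for banding, edgeR called up to 303 genes and DESeq2 up to 727. The simulated false calls may therefore be too few for the real libraries.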

Results

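Messenger RNA was counted per gene in left ventricle and skeletal muscle of cats with aortic banding, a feline model of heart failure with preserved ejection fraction per the labels, and of sham-operated cats. Each tissue gave 18 libraries, with 3 libraries of sham at 1 month and 5 libraries in each of the other 3 groups. The series addresses changes in these tissues as the disease progresses, so banding at each time, time in each treatment and the difference between the tissues were compared. Left ventricle libraries held 19.1 M gene counts on average (SD 2.28 M, n = 18), with 15649 to 16427 genes detected. Skeletal muscle libraries held 27.6 M gene counts (SD 2.86 M, n = 18), with 15158 to 16319 genes detected. The 10 most abundant genes took 13.4% to 20.4% of the counts in left ventricle and 25.4% to 36.7% in skeletal muscle.

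In both tissues the first principal component separated 1 month from 4 months. It held 36.3% of the variance in left ventricle and 41.6% in skeletal muscle. In left ventricle the sham and banded libraries of 1 month lay between -55.3 and -42.5, and those of 4 months between 25.6 and 55.0. In skeletal muscle they lay between -67.4 and -43.1 at 1 month and between 12.7 and 63.3 at 4 months.

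**Figure D1:**
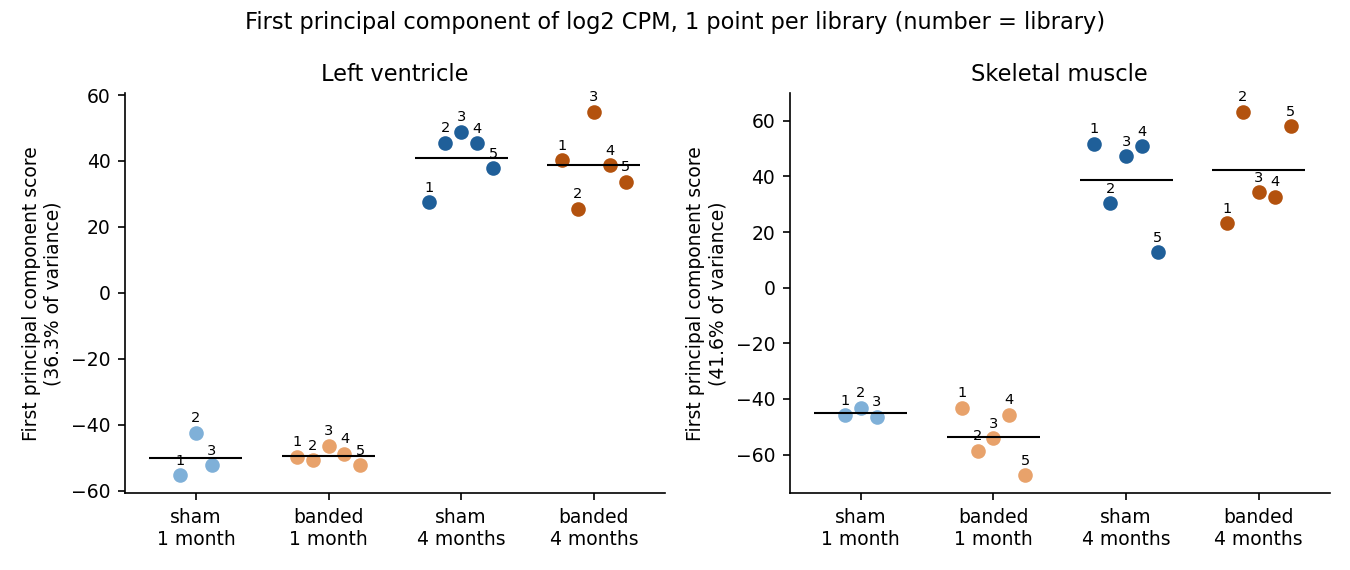
First principal component of log2 CPM for each library, by group, in left ventricle and skeletal muscle. Each point is 1 library. All 1-month libraries lie below 0 and all 4-month libraries above 0 in both tissues.

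Banding for 1 month was compared with sham in left ventricle to ask which genes differ early in the model. No gene passed an adjusted p of 0.05 with edgeR, and the smallest adjusted p was 0.124. At an unadjusted p under 0.05 there were 1216 genes, where 699 are expected by chance among 13976 genes. DESeq2 called 100 genes, 13 higher and 87 lower in banded animals, and voom without quality weights called 0. ENSFCAG00000010822 stood at 47.2 CPM in banded libraries (SD 2.97, n = 5) and at 68.8 CPM in sham libraries (SD 4.72, n = 3). All 5 banded libraries lay below all 3 sham libraries, with a log2 fold change of -0.54 (SE 0.107, adjusted p 0.124 with edgeR). The gene was chosen after its values were seen, so this separation gives no support of its own. DESeq2 called this gene with an adjusted p of 0.000798, and its adjusted p ran from 0.000407 to 0.821 over the alternatives. The count with edgeR rested on single libraries. It was 571 without sham library 2, with 305 higher and 266 lower, and 62, all lower, without banded library 2. Voom with quality weights called 2430 genes. Its weights for sham libraries 1, 2 and 3 were 3.4, 0.204 and 1.02. Its sham mean thus rested most on library 1.

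Banding for 4 months was compared with sham in left ventricle to ask which genes differ later in the model. No gene passed with edgeR, where the smallest adjusted p was 0.0579, and 1420 genes had an unadjusted p under 0.05 with 699 expected by chance. DESeq2 called 135 genes, 95 higher and 40 lower in banded animals, and voom called 1 with quality weights and 1 without. ENSFCAG00000046690 stood at 501.9 CPM in banded libraries (SD 46.3, n = 5) and at 227.3 CPM in sham libraries (SD 64.5, n = 5), a 2.21-fold difference with a log2 fold change of 1.14 (SE 0.176, adjusted p 0.0579 with edgeR). All 5 banded libraries, from 455.1 to 556.4 CPM, lay above all 5 sham libraries, from 154.7 to 318.3 CPM. This separation gives no support of its own, since the gene was chosen after its values were seen. With DESeq2 the adjusted p of ENSFCAG00000046690 was 3.02e-06. It ran from 1.19e-11 to 0.295 over the alternatives, the lowest with DESeq2 and sham 1-month library 1 in place of sham 4-month library 1. Without sham library 1 and without sham library 3 its adjusted p was 0.00679 and 0.0486, and without banded library 1 it was 0.0381. The edgeR count was 2 without sham library 1, 2 without sham library 3, 1 without sham library 5, 5 without banded library 1 and 1 without banded library 3. Banded libraries held 17.4 M gene counts (from 14.6 M to 20.7 M, n = 5) and sham libraries 21.2 M (from 19.5 M to 22.3 M, n = 5), with an exact permutation p of 0.0317 that became 0.571 after correction over the library measures.

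**Figure D2:**
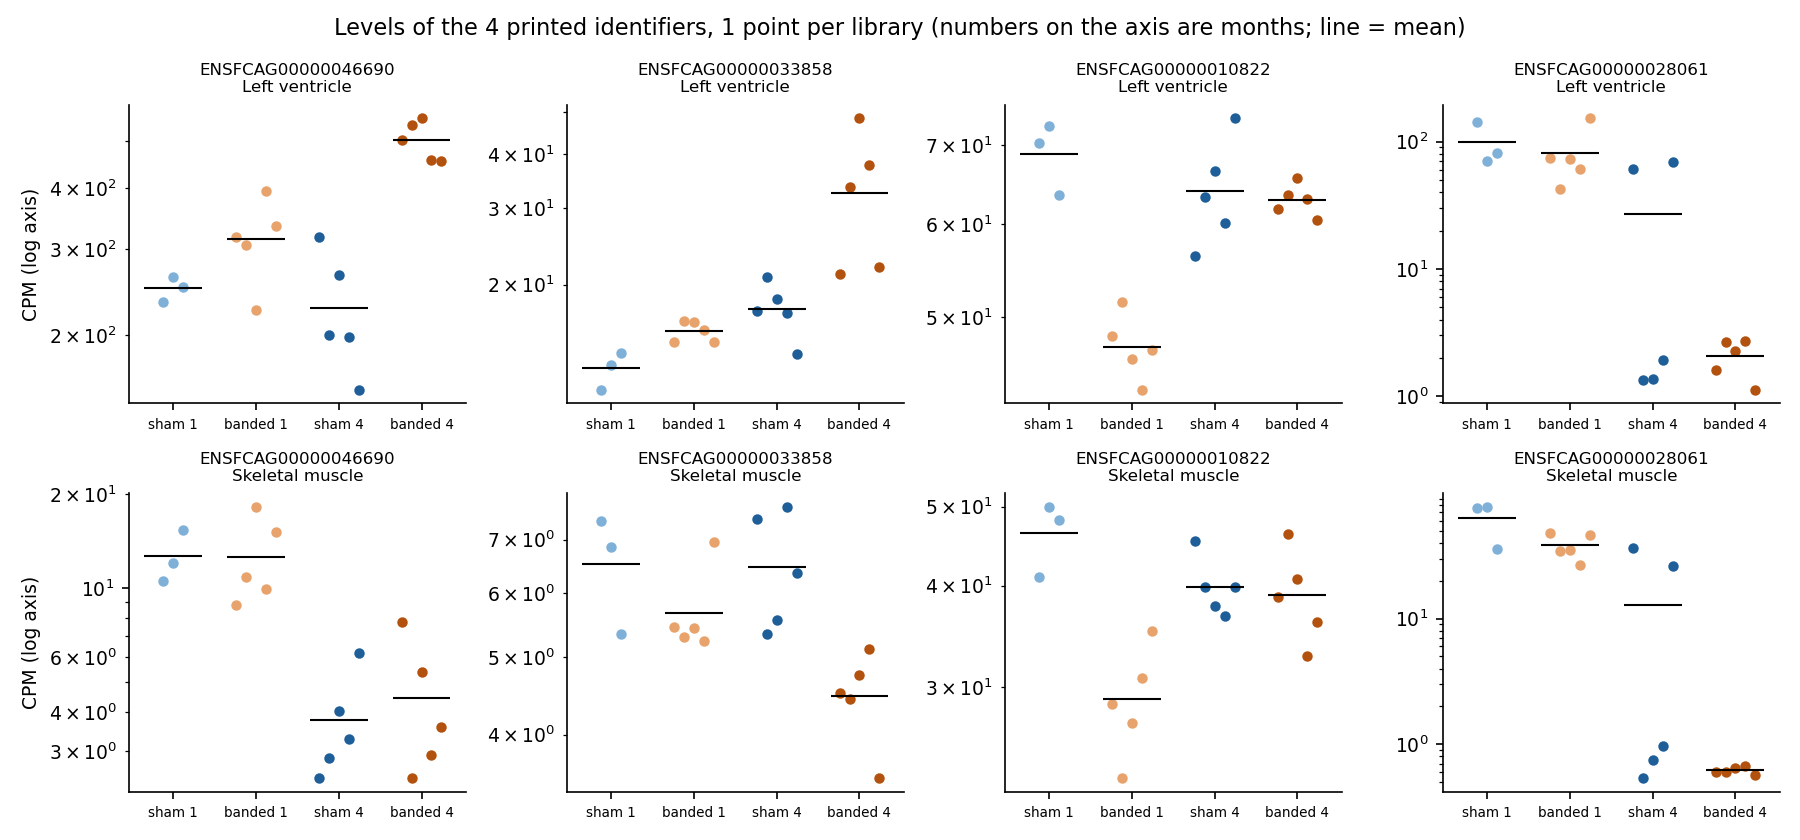
Levels (CPM) of the 4 identifiers named in the text, on a log axis, by group and tissue. Each point is 1 library and each line is a group mean. ENSFCAG00000046690 in left ventricle at 4 months stands at 455.1 CPM or more in banded libraries and at 318.3 CPM or less in sham libraries.

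ENSFCAG00000028061 had levels far apart within the sham group at 4 months. In left ventricle, sham libraries 1 and 5 stood at 60.5 and 69.7 CPM, while sham libraries 2, 3 and 4 lay between 1.35 and 1.92 CPM and all 5 banded libraries between 1.13 and 2.71 CPM. The skeletal muscle libraries with the same numbers split in the same way, with sham libraries 1 and 5 at 36.4 and 26.03 CPM, sham libraries 2, 3 and 4 at 0.965 CPM or less and banded libraries at 0.676 CPM or less. The log2 fold change of banding at 4 months was -3.70 in left ventricle (SE 0.958, adjusted p 0.21 with edgeR and 0.013 with DESeq2, from 0.00346 to 0.792 over the alternatives) and -4.38 in skeletal muscle (SE 0.976, adjusted p 0.231 with edgeR and 0.00104 with DESeq2, from 0.000331 to 0.742). With voom and quality weights it was -0.98 in left ventricle and -1.83 in skeletal muscle, and -1.70 and -2.49 without weights. The adjusted p of 0.00346 in left ventricle came from DESeq2 with sham 1-month library 1 in place of sham 4-month library 1. From 1 to 4 months in banded animals the gene fell by 5.29 on the log2 scale in left ventricle (adjusted p 0.0011) and fell by 5.93 in skeletal muscle (adjusted p 0.000305).

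Time was compared in sham left ventricle to give the change between 1 and 4 months without banding. In the 2552 genes called by edgeR, 1235 were higher and 1317 lower at 4 months, and 1472 of them changed more than 2-fold. The median size of the called changes was 1.12 on the log2 scale. DESeq2 called 3146 genes, and 2541 were called by both tools. The count depended on the sham libraries of 1 month, with 1525 genes without library 1 and 1601 without library 3. It was 1508 in a fit of the sham groups alone and 6001 with voom and quality weights.

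In banded left ventricle, edgeR called 3550 genes between 1 and 4 months, 1788 higher and 1762 lower at 4 months, with a median size of 0.96 on the log2 scale. DESeq2 called 4056, and 3536 were called by both. The changes with time in sham and banded animals went together across genes (Pearson r = 0.765, Spearman rho = 0.727, 13976 genes). Of the genes called in both treatments, 885 were higher in both, where 158 are expected by chance, 912 were lower in both, where 166 are expected, and 4 went in opposite directions, where 324 are expected. The banding effect at 4 months minus that at 1 month, which is also the difference between the time effects, gave 0 genes with edgeR and 885 at an unadjusted p under 0.05. DESeq2 called 3 genes, voom without quality weights 0 and voom with quality weights 506, and edgeR called 53 without sham 1-month library 2. The labels give no batch or date, so time and a possible sequencing batch cannot be separated.

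Skeletal muscle was compared in the same way, as a tissue outside the heart. Banding for 1 month gave 0 genes with edgeR, 1898 at an unadjusted p under 0.05 with 674 expected by chance, and a smallest adjusted p of 0.0852. DESeq2 called 24 genes, 12 higher and 12 lower, voom without quality weights 0 and voom with quality weights 1456. The weights of sham 1-month libraries 1, 2 and 3 were 0.828, 5.18 and 0.731, so the weighted sham mean rested most on library 2. ENSFCAG00000010822 stood at 29.0 CPM in banded libraries (SD 4.44, n = 5) and 46.4 CPM in sham libraries (SD 4.75, n = 3), with all 5 banded libraries below all 3 sham libraries. As this gene was chosen after its values were seen, the separation gives no support of its own. Its log2 fold change was -0.68 (SE 0.134, adjusted p 0.278 with edgeR and 0.0121 with DESeq2, from 0.00682 to 0.748 over the alternatives). Leaving out sham library 1, sham library 3, banded library 1 or banded library 4 gave 1, 2, 1 and 1 genes with edgeR.

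Banding for 4 months in skeletal muscle gave 0 genes with edgeR, 1063 at an unadjusted p under 0.05 with 674 expected by chance, and a smallest adjusted p of 0.0816. DESeq2 called 56 genes, 9 higher and 47 lower in banded animals, and voom called 0 with and without quality weights. The edgeR count was 22 without banded library 1, with 3 higher and 19 lower, and 6, all lower, without sham library 5.

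Time was compared in skeletal muscle in both treatments. In sham animals edgeR called 3404 genes, 1488 higher and 1916 lower at 4 months, with a median size of 0.93 on the log2 scale, and DESeq2 called 3992, of which 3349 were shared. The edgeR count was 2182 without sham 1-month library 2, 1998 without sham 1-month library 3 and 6290 with voom and quality weights. In banded animals edgeR called 5746 genes, 2623 higher and 3123 lower, with a median size of 0.90, and DESeq2 called 6105, of which 5697 were shared. The time effects of sham and banded animals correlated across genes (r = 0.733, rho = 0.723, 13480 genes), with 1090 genes higher in both where 290 are expected, 1409 lower in both where 444 are expected, and 4 in opposite directions where 718 are expected. The difference between these time effects gave 0 genes with edgeR, 1699 at an unadjusted p under 0.05, 13 with DESeq2, 0 with voom without quality weights and 61 with quality weights. Without banded 1-month library 4, edgeR called 1.

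**Figure D3:**
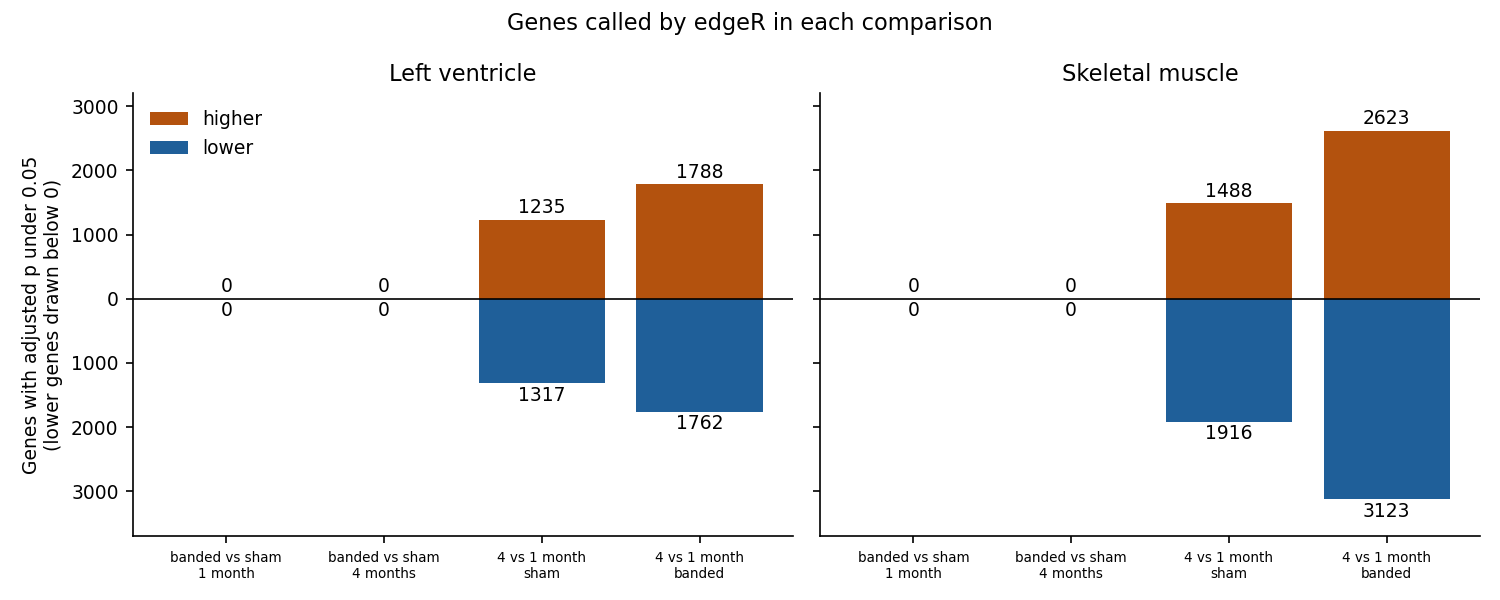
Genes called at an adjusted p under 0.05 by edgeR in each comparison, with genes higher drawn above 0 and genes lower drawn below 0, for left ventricle and skeletal muscle. The bars for time hold 2552 to 5746 genes in all, and the bars for banding at 1 and 4 months stand at 0.

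The time effects of the tissues were compared with each other across 12990 genes tested in both. Genes that changed in the same direction in sham and banded animals of a tissue were taken from each. Of these, 141 were higher at 4 months in both tissues where 66.7 are expected by chance, and 358 were lower in both where 90.4 are expected. Another 13 were higher in left ventricle and lower in skeletal muscle, where 86.1 are expected, and 7 the opposite, where 70.0 are expected. The correlation across genes was 0.465 in sham and 0.412 in banded animals, and 0.242 between sham left ventricle and banded skeletal muscle, which share no group.

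**Figure D4:**
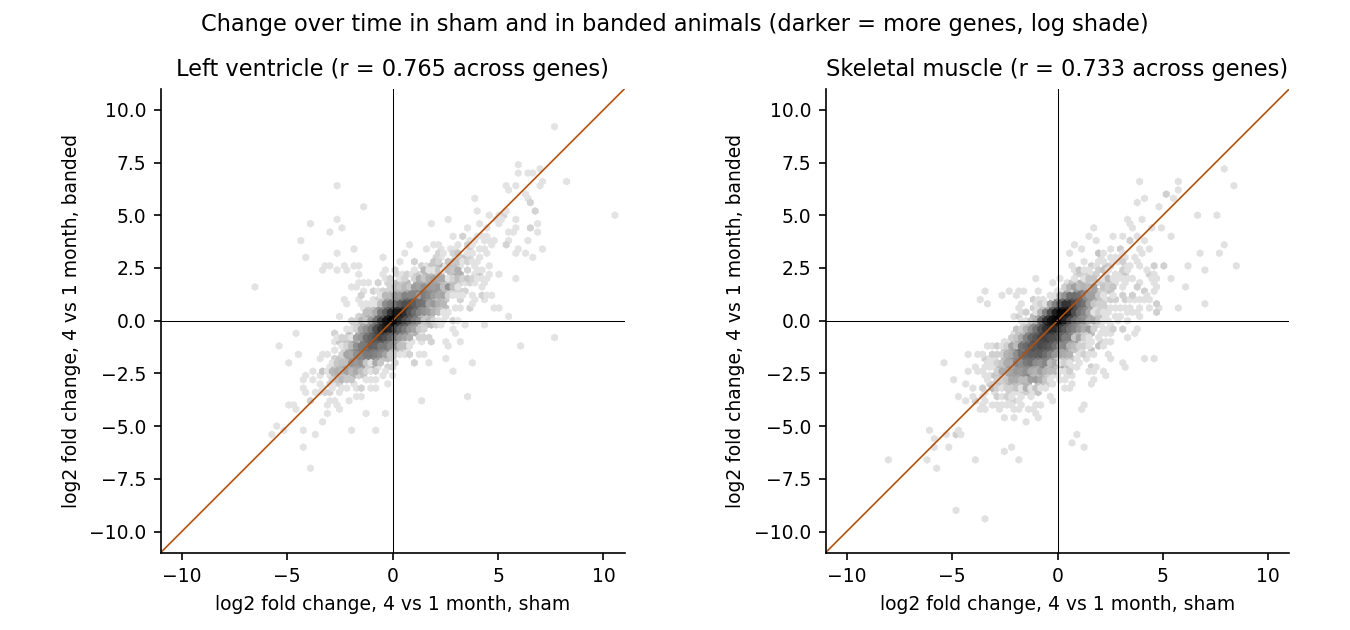
Log2 fold change from 1 to 4 months in banded animals against that in sham animals, for genes tested in left ventricle and skeletal muscle. Shade gives the number of genes on a log scale and the diagonal marks equal changes, and the correlation across genes is 0.765 in left ventricle and 0.733 in skeletal muscle.

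The banding effects were compared between times and tissues across genes. Over 9 correlations of fold changes computed, those of banding were 0.165 between 1 and 4 months in left ventricle (0.0472 to 0.263 with 1 library left out) and -0.0675 in skeletal muscle (-0.155 to 0.0267). The ranges with 1 library left out are not confidence intervals and do not give the sampling error of a correlation. Between the tissues the correlations of banding effects were 0.338 at 1 month (0.228 to 0.362, Spearman rho 0.241) and 0.0881 at 4 months (0.0499 to 0.126). In genes with a mean of 10 CPM or more, r at 1 month was 0.23 and Spearman rho 0.109. If the tissues come from the same animals, differences between animals enter the effects of both tissues. A correlation between the tissues can then arise without banding, which was not tested. The difference between the tissues itself was tested in 14579 genes. At 1 month edgeR called 0 genes, with 1133 at an unadjusted p under 0.05, DESeq2 2, voom without quality weights 0 and voom with quality weights 1521. The edgeR count was 1 with the library number as a block across the tissues, 276 without left ventricle sham library 2 and 8 without left ventricle banded library 2.

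At 4 months the banding effect differed between left ventricle and skeletal muscle in 5 genes with edgeR, in a fit that takes the libraries of the tissues as independent, all with a higher effect in left ventricle, and 1163 genes had an unadjusted p under 0.05. With the library number as a block across the tissues, as for tissues of the same animals, edgeR called 1 gene. DESeq2 called 22 genes, 19 of them with a higher effect in left ventricle. ENSFCAG00000033858, chosen from the 5 after the values were seen, had the smallest p, with a difference of 1.45 on the log2 scale (SE 0.241, adjusted p 0.0138, from 0.000172 to 0.0856 over the alternatives). With the block the difference was 1.39 and the adjusted p 0.0808, so it was not called. In left ventricle it stood at 32.5 CPM in banded (SD 11.4, n = 5) and 17.6 CPM in sham libraries (SD 2.55, n = 5). In skeletal muscle it stood at 4.47 CPM in banded (SD 0.586, n = 5) and 6.47 CPM in sham libraries (SD 1.06, n = 5). In the tissues taken alone, the adjusted p with edgeR was 0.174 in left ventricle and 0.309 in skeletal muscle. DESeq2 called it in left ventricle, with an adjusted p of 0.00679 (0.00372 to 0.416 over the alternatives), and not in skeletal muscle, with 0.0919 (0.0847 to 0.722). The 0.00372 came from DESeq2 with sham 1-month library 1 in place of sham 4-month library 1. The count was 1 with voom and quality weights and 0 without them. It was 0 without left ventricle sham library 5 or skeletal muscle banded library 5, where the adjusted p of ENSFCAG00000033858 was 0.0508 and 0.0543, and 16 without skeletal muscle banded library 1. It lay at 1 to 3 without any 1 of left ventricle sham libraries 2 and 4, left ventricle banded libraries 2 and 4, skeletal muscle sham libraries 2 and 3, or skeletal muscle banded libraries 3 and 4.

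The authors' deposited tables list 13791 genes in left ventricle and 13368 in skeletal muscle. At an adjusted p under 0.05 the authors' deposited tables hold, in left ventricle, 77 genes for banding at 1 month, 128 for banding at 4 months, 971 for time in sham and 3671 for time in banded animals. In skeletal muscle the authors' deposited tables hold 8, 87, 1046 and 5896 genes in the same order. In the authors' deposited tables of sham time, 83.0% of the called genes in left ventricle and 71.2% in skeletal muscle were higher at 4 months. DESeq2 on the deposited counts of the same genes called 3140 genes for sham time in left ventricle and 3981 in skeletal muscle. Across genes, log2 fold changes from the deposited counts correlated with those of the authors' deposited tables at 0.9997 or more in the comparisons without sham 4 months. For banding at 4 months they correlated at 0.874 in left ventricle and 0.825 in skeletal muscle, and for sham time at 0.973 and 0.969.

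The mean normalized counts of the authors' deposited tables were fitted as weighted sums of the deposited libraries over all genes listed there. In left ventricle 16 libraries had weights from 1 to 1.004, sham 1-month library 1 had 2.007 and sham 4-month library 1 had 0. In skeletal muscle 16 libraries had weights from 0.992 to 0.998, sham 1-month library 1 had 1.991 and sham 4-month library 1 had 0. With the counts of sham 1-month library 1 put in place of sham 4-month library 1, DESeq2 gave 128 genes for banding at 4 months and 966 for sham time in left ventricle, and 87 and 1013 in skeletal muscle. With edgeR and the same replacement, sham time gave 223 genes in left ventricle and 0 in skeletal muscle, where 3149 had an unadjusted p under 0.05 and DESeq2 called 1021 over the genes edgeR kept.

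**Figure D5:**
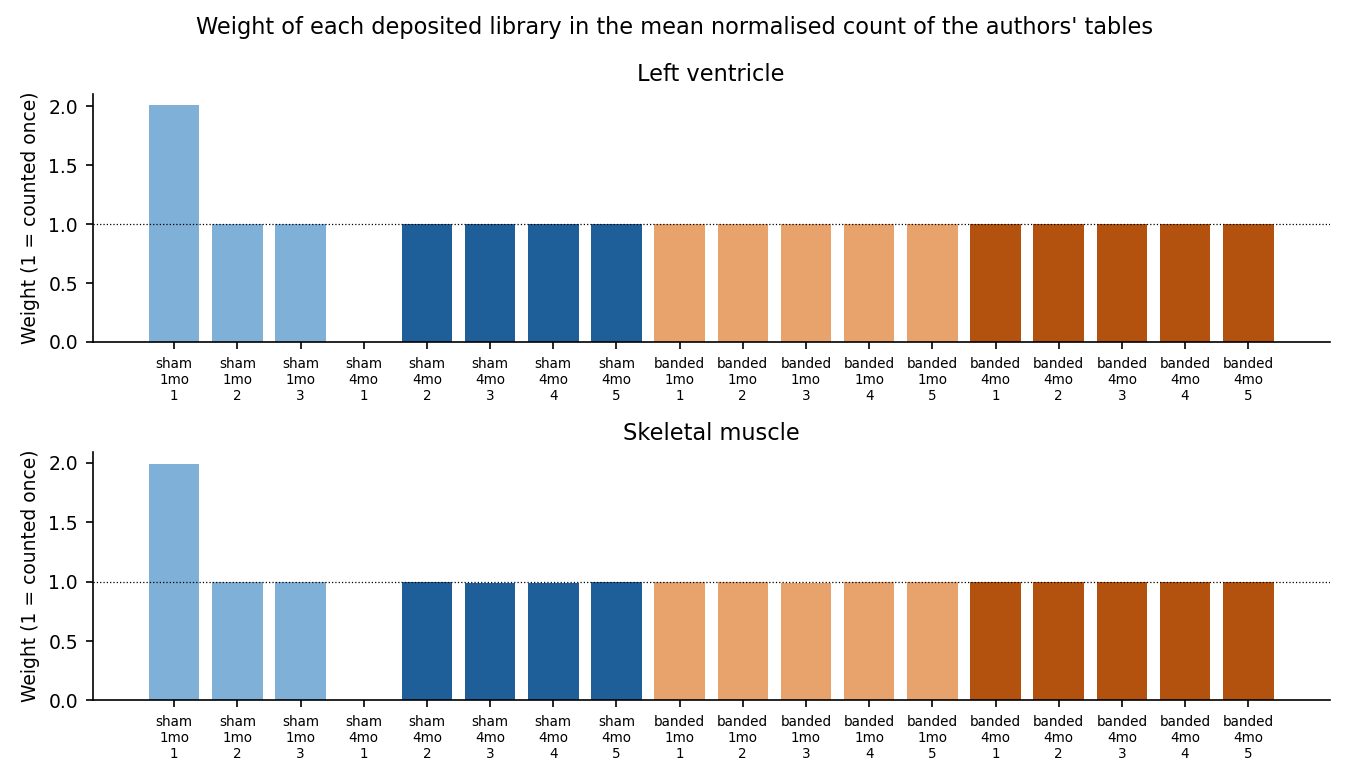
Weight of each deposited library in the mean normalized counts of the authors' tables, in left ventricle and skeletal muscle. Each bar is 1 library. Sham 1-month library 1 stands near 2 and sham 4-month library 1 at 0, in both tissues.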

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

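The tests on the authors' tables, the fit with voom without quality weights and the tests on left ventricle sham 1-month library 2 and on genes with 2 levels were chosen after the results were seen. The comparison of banding effects between the tissues was fixed beforehand.

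At 4 months the banding effect differed between the tissues in 5 genes, all with a higher effect in left ventricle, by the test of the difference with edgeR in a fit that takes the libraries of the tissues as independent. With the library number as a block across the tissues the count was 1, and ENSFCAG00000033858, which had the smallest p without it, was not called (adjusted p 0.0138 without and 0.0808 with the block). The count with DESeq2 was 22, and that with voom was 1 with quality weights and 0 without, where 993 genes had an unadjusted p under 0.05. With edgeR it was 0 without left ventricle sham library 5 or without skeletal muscle banded library 5, with 1233 and 989 genes at an unadjusted p under 0.05, and 16 without skeletal muscle banded library 1. It was 3 without left ventricle sham or banded library 2, 2 without left ventricle banded library 4, skeletal muscle sham library 2 or 3 or skeletal muscle banded library 4, and 1 without left ventricle sham library 4 or skeletal muscle banded library 3.

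In 54 tests, each of 1 measure in 1 group of 5 libraries, 2 found a library far from the others, and 2.7 are expected by chance. The measures come from the same libraries, so the tests are not independent. Skeletal muscle banded 1-month library 1 had 59.1% of its reads assigned to genes, and the other 4 had 71.0% to 73.2%. Skeletal muscle banded 1-month library 5 had 6.96 CPM of ENSFCAG00000033858, and the other 4 had 5.23 to 5.44 CPM.

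The authors' tables give sham 4-month library 1 a weight of 0 in both tissues and sham 1-month library 1 a weight of 2.007 in left ventricle and 1.991 in skeletal muscle. Against a difference in normalization or filtering, the tables' fold changes departed from the deposited counts in the comparisons with sham 4 months, where the lowest r was 0.825, and not in the others, where r was 0.9997 or more. Against a deposited sham 4-month library 1 that came from 1 month, its first principal component was 27.5 in left ventricle and 51.8 in skeletal muscle, while the highest 1-month library stood at -42.5 and -43.1. A candidate explanation is that sham 1-month library 1 was counted in place of sham 4-month library 1 in both tissues, since DESeq2 with that replacement gave fold changes whose median difference from the tables was 2.28e-07 at most. How this arose is open, and no biological explanation was tested, since the same library is absent from tables of both tissues.

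Left ventricle banding at 1 month gave 0 genes with edgeR (1216 at an unadjusted p under 0.05, 100 with DESeq2, 2430 and 0 with voom with and without quality weights), 571 without sham library 2 and 62 without banded library 2, and the log2 levels of sham library 2 departed from the other sham libraries with an SD of 0.902, against 0.446 to 0.714 for the other left ventricle libraries. A banded library under a sham label stays open: on 500 genes chosen without it this library lay at 122% of the way from the other sham to the banded libraries, beyond the 78.5% to 97.9% of left-out banded libraries, and this place does not separate a wrong label from a trait that sham libraries 1 and 3 share, while its median distance of 0.805 to the banded libraries, though below its 0.952 to the other sham libraries, was above the 0.71 that a banded library reached at most. Against skeletal muscle RNA, its median level of 65 genes chosen as abundant in skeletal muscle was 0.543 CPM, within 0.452 to 1.17 CPM in the other left ventricle libraries, and against a few genes taking most of the counts, its 10 most abundant genes held 17.0%, within 13.4% to 20.4%. RNA quality, the site sampled within the ventricle and a difference between animals stay open as untested, as does an effect of banding, so the 571 genes may reflect banding or a trait that sham libraries 1 and 3 share.

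In 21 genes the levels fell into 2 sets more than 1.5 apart on the log2 scale in both tissues. In 15 of them the same library numbers were high in left ventricle and skeletal muscle, and in the rest the numbers differed. Against noise of single libraries, shuffling the numbers within groups gave at most 8 such genes in 1000 shuffles. Against banding or time as the cause in the largest set, its 8 genes had both levels in 4 of 4 groups, with 1 of 3 sham and 3 of 5 banded libraries high at 1 month and 2 of 5 sham and 4 of 5 banded libraries high at 4 months, and took 5.00% to 8.49% of the left ventricle counts when high and 0.168% to 0.257% when low. Of the other 7 genes, 6 had both levels in at least 2 groups, which does not exclude a part of banding or time in them. ENSFCAG00000004010 was high for 5 of 8 library numbers at 1 month and 10 of 10 at 4 months (Fisher's exact p 0.0686, and 0.455 after correction). Time also stays open for ENSFCAG00000028061, which was high for 8 of 8 library numbers at 1 month and 2 of 10 at 4 months (Fisher's exact p 0.00105, and 0.0158 after correction over the 15 genes). This is in line with both tissues coming from the same animals and with a difference between animals, such as a genetic variant against the reference (the 8 genes lie within 30 listed identifiers in a row, which does not give their place in the genome), which cannot be told apart from other lasting differences because neither the genome nor the sex of the animals is at hand.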

How the results depend on the processing

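Voom without quality weights and the fits with sham 1-month library 1 in place of sham 4-month library 1 were chosen after seeing the data, as were the alternatives for correlations of time effects and the left-out libraries for all correlations. Of 236 alternative counts, 169 equalled the count reported or lay within 1.5 times of it. Most of the 169 were counts of 0 where the count reported was also 0. Of 185 alternative values of the 4 identifiers, 160 kept their side of the threshold and 0 changed direction. The counts for time in banded animals stayed within 1.5 times under every alternative run, from 2663 to 3410 in left ventricle (LV) and 4945 to 5685 in skeletal muscle (SKM) with 1 library left out. Scaling by RLE moved no count by more than 1.5 times.

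DESeq2 called 100 and 135 genes for LV banding at 1 and 4 months, 3 for the LV difference between times, 24 and 56 for SKM banding at 1 and 4 months, 13 for the SKM difference between times, and 2 and 22 for the difference between tissues at 1 and 4 months. Voom with quality weights called 2430, 1, 6001 and 506 genes for LV banding at 1 and 4 months, sham time and the difference between times, 1456, 6290 and 61 for SKM banding at 1 month, sham time and the difference between times, and 1521 and 1 for the difference between tissues. Voom without weights called 1 for LV banding at 4 months and 0 for the tissue difference at 4 months, where 993 had an unadjusted p under 0.05. Without a low-count filter, LV banding at 4 months and SKM banding at 1 month gave 1 gene each. A fit of the sham groups alone gave 1508 genes for LV sham time. With replicate number as a block, SKM banding at 4 months gave 1, and with the number as a block across tissues the tissue difference gave 1 at each time, with an adjusted p of 0.0808 for ENSFCAG00000033858 at 4 months (0.000172 to 0.0856 over the alternatives). Voom without weights called 2569 genes for LV sham time and 3326 for SKM sham time. It called 0 for banding at 1 month and for the difference between times, in LV and in SKM. Only the weights differ between the voom fits, so these larger counts with quality weights depend on the weights. The cause of the other changes was not tested.

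With sham 1-month library 1 in place of sham 4-month library 1, edgeR gave 1 and 223 genes for LV banding at 4 months and sham time, and 1 and 0 in SKM, where 3149 had an unadjusted p under 0.05. DESeq2 gave 118, 964 and 1 for LV banding at 4 months, sham time and the difference between times, and 84, 1021 and 2 in SKM. A group that holds a library of the other group by construction has a smaller difference from it.

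Leaving out 1 library in turn gave 0 to 571 genes for LV banding at 1 month (571 without sham library 2, 62 without banded library 2), 0 to 5 at 4 months (5 without banded library 1, 2 without sham library 1 or 3, 1 without sham library 5 or banded library 3), 1525 to 3715 for LV sham time (1525 without 1-month library 1, 1601 without 3) and 0 to 53 for the LV difference between times (53 without sham 1-month library 2). In SKM it gave 0 to 2 for banding at 1 month (2 without sham library 3, 1 without sham library 1, banded library 1 or 4), 0 to 22 at 4 months (22 without banded library 1, 6 without sham library 5), 1998 to 3632 for sham time (1998 without 1-month library 3, 2182 without 2) and 0 to 1 for the difference between times (1 without banded 1-month library 4). The tissue difference gave 0 to 276 genes at 1 month (276 without LV sham library 2, 8 without LV banded library 2) and 0 to 16 at 4 months. The gene lists, their alternatives and the named genes were not run, since no identifier has a symbol. In counts simulated independently per gene at this depth and number of libraries, edgeR recovered at most 56.7% of 2-fold changes.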

Other observations

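The time score and its test, and the split without left ventricle sham library 2, were chosen after the results were seen. The other splits of the samples were fixed before the data were examined.

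A score of time was computed per library as the mean log2 CPM of genes that were higher at 4 months in both treatments of the other tissue, minus that of genes that were lower. In left ventricle, scored with 1050 and 1356 genes taken from skeletal muscle, it rose from 0.85 (SD 0.181, n = 3) to 1.81 (SD 0.134, n = 5) in sham animals, with an exact permutation p of 0.0179, and from 0.72 (SD 0.0864, n = 5) to 1.80 (SD 0.17, n = 5) in banded animals, with an exact permutation p of 0.00794. In skeletal muscle, scored with 825 and 866 genes taken from left ventricle, it rose from 0.54 (SD 0.059, n = 3) to 1.89 (SD 0.428, n = 5) in sham animals and from 0.50 (SD 0.0769, n = 5) to 1.46 (SD 0.448, n = 5) in banded animals, with exact permutation p of 0.0179 and 0.00794, which are the smallest these group sizes can give. The genes come from the other tissue, and if the tissues come from the same animals the score is not independent of it. The hypothesis that banding may move the animals along this program of time was tested in 4 comparisons. Banded libraries differed from sham by -0.13 and -0.01 in left ventricle at 1 and 4 months, and by -0.04 and -0.43 in skeletal muscle, with a smallest exact permutation p of 0.175 and of 0.428 after correction. The test does not settle the hypothesis, since a difference of this size lies within the spread between libraries.

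Other splits of the same samples were fitted to ask whether chance can be excluded, with 56 splits of 3 against 5 libraries and 100 drawn splits elsewhere, the real one included. For time, the real split gave the most genes with edgeR. In left ventricle, sham time gave 2552 genes and the highest other split 1867, and banded time 3550 and 236. In skeletal muscle, sham time gave 3404 and 337, and banded time 5746 and 1131. In each of these 4 comparisons 1 split, the real one, gave as many. The share was 1 of 56 for sham time and 1 of 100 for banded time, the smallest these splits can give. These shares are under 0.05 and argue against chance. They are not corrected for the comparisons split with edgeR, so they do not firmly exclude it.

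For banding, chance cannot be excluded with edgeR from the genes at an unadjusted p under 0.05. In left ventricle, 10 of 56 splits gave as many as the real 1216 at 1 month, with 2904 as the highest other, and 5 of 100 as many as 1420 at 4 months, with 1817. In skeletal muscle, 6 of 56 gave as many as 1898 at 1 month, with 2582, and 22 of 100 as many as 1063 at 4 months, with 1917. For the difference between times, 33 of 100 gave as many as 885 in left ventricle, with 2893, and 6 of 100 as many as 1699 in skeletal muscle, with 2161. For the difference between tissues, 24 of 100 gave as many as 1133 at 1 month, with 2968, and 5 of 100 as many as the 5 genes called at 4 months, with 122. The splits for this difference regrouped each tissue separately, so libraries with the same number could fall in different groups. If the tissues come from the same animals, these splits do not keep that pairing. Some splits gave several times the real count, such as 303 genes called for skeletal muscle banding at 4 months against 0 with the real split, which may point to a structure of the samples, though what these splits share was not tested.

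With DESeq2, 4 of 100 splits gave as many as 135 genes for left ventricle banding at 4 months, with 230 as the highest other. This share is under 0.05, but it is not corrected for the 4 banding comparisons split in this way with DESeq2, so it does not firmly exclude chance. Chance cannot be excluded at 1 month, where 5 of 56 splits gave as many as 100, with 727. In skeletal muscle it cannot be excluded either, where 15 of 56 gave as many as 24 at 1 month, with 530, and 11 of 100 as many as 56 at 4 months, with 563. Without left ventricle sham library 2, banding at 1 month gave 571 genes with edgeR, and 1 of 21 splits, the real one, gave as many, with 14 as the highest other. This does not exclude chance, since the library was left out for its effect on the real count and no library was chosen in that way for the other splits.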
